A study of Homo sapiens with 24 samples.

How the data were processed

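Chromatin immunoprecipitation sequencing (ChIP-seq) was described for 24 samples from 6 established human breast cancer cell lines. JARID1B (also called KDM5B, an enzyme that removes methyl groups from lysine 4 of histone H3), dimethylated and trimethylated H3 lysine 4 (H3K4me2 and H3K4me3) and CTCF (a DNA-binding protein of insulators and chromatin loop ends) were the 4 targets. Peak lists were used for 18 samples, and the 6 input samples were not analysed here. Per the labels' protocols, cells were transfected with siRNA pools and cultured for 5 days before chromatin was prepared, cross-linked with formaldehyde and sonicated. The HCC2157 H3K4me2 and H3K4me3 samples carry no transfection label and are called control samples.

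Per the submitters' processing notes, CASAVA 1.7, Bowtie and MACS2 were used with genome build hg19. The role of each tool, the read filters and the use of the input samples are not given in the sources used here, nor are the versions of Bowtie and MACS2. Each deposited list is assigned to 1 sample, and whether any reads were pooled before calling is not given in the sources used here. Each list has 6 columns and no header, with the interval in the first columns and a whole-number score per peak in the fifth. The score is the authors' deposited value. It was at least 30 in 17 lists and 1 for each peak of the HCC2157 JARID1B list, which therefore could not be ranked. Its unit is not given in the sources used here, and it was used only to rank peaks within a list. Neighbouring peaks were at least 51 bp apart within every list, and between 3 and 13 peaks per list were shorter than the length that the list's name carries, so the lists appear to have been filtered on width and joined across short gaps. Read depth is unknown from such lists, and the number of peaks in a list also depends on depth, enrichment and threshold.

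Intervals on chromosomes 1 to 22 and X were kept, and an interval repeated within a list was used once, with its highest score. Repeated intervals occurred in 10 lists. Peaks overlapped when they shared at least 1 bp. Each group had 1 library, so there is no replicate check and no p-value for any comparison of 2 lists. Percentages are given with 95% Wilson intervals, which cover counting error over peaks only. The chance level is the mean of 100 placements of the other list's peaks at random within the same chromosome, in 1 Mb windows that hold a peak of any of the 18 lists. Unmappable sequence inside those windows was not excluded. Differences between classes of peaks within a list are given with 95% intervals from 1000 bootstrap draws of 10 Mb blocks. These intervals describe the libraries, not the conditions. Subtypes were compared on 4 measures per line with two-sided exact permutation tests and Benjamini-Hochberg adjustment. Overlapping intervals of several lists were joined into merged regions for comparisons of 3 or 6 lines.

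The reference table given for gene names is on another assembly than the lists, GRCh38.p14, so its coordinates were not used and peaks were not assigned to genes. Comparisons planned for gene promoters were made on merged regions, as the plan provided, and promoter windows of other widths were not run. The 23 gene lists fixed before the data were examined were not analysed here for the same reason. Regions are named by position in hg19, counted from 1, under a rule fixed before the data were examined. For each pair of lists of 1 antibody, the rule takes the 5 highest-scored peaks of each list that the other lacks. For the 6 lines it takes 8 regions for each subtype and 5 found in all lines, by mean rank percentile over the lists with scores. For each pair of antibodies in 1 line, it takes the 5 shared regions with the highest mean rank percentile. The first regions under each part are printed. Luminal and basal subtypes come from background knowledge of the established lines, not from the labels.

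CTCF was measured in SUM159PT only, and its peaks there served as a map of CTCF sites for all lines. H3K4me3 was measured in 3 lines. The MCF7 list was used for the retention of MCF7 peaks after knockdown, and peaks of any of the 3 lines for SUM185PE and for comparisons across lines. Peaks of any of the 3 lines were also used for differences in share, siCTCF minus siControl, in MCF7 as well. These maps are approximate where the line differs. The overlap measures were tested on simulated data. With 30% and 70% of the 18169 MCF7 siControl JARID1B peaks planted in a simulated list, 30.5% and 70.4% were recovered, and 200 of 200 regions planted in 3 of 6 simulated lists were recovered. Planted peaks kept their widths and moved by a small part of them, and planted regions kept their positions. Recovery was therefore near certain, and it checks the computation rather than lists whose peak edges differ.

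Alternatives fixed before the data were examined were a reciprocal overlap of 50%, a midpoint rule, the peaks at or above each list's median score, lists of equal length by score, and removal of the 1% of 1 Mb windows with the most peaks. For the 6 lines, each line was also left out in turn. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.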

Results

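The data are 18 peak lists, each from 1 ChIP-seq library of a breast cancer cell line. MCF7, T-47D and SUM185PE are luminal lines, and SUM159PT, MDA-MB-231 and HCC2157 are basal lines. JARID1B was mapped in 9 libraries, H3K4me2 in 4, H3K4me3 in 4 and CTCF in 1. H3K4me3 marks active promoters, H3K4me2 marks promoters and enhancers, and JARID1B removes both marks. JARID1B lists under siControl held 18169 peaks in MCF7, 39777 in T-47D, 3739 in SUM185PE, 20256 in SUM159PT, 35434 in MDA-MB-231 and 25917 in HCC2157. Median JARID1B peak widths under siControl lay between 148 bp in SUM185PE and 183 bp in MCF7, against 766.5 bp for H3K4me3 in MCF7. With 1 library per group there is no replicate error, and each interval covers counting error over peaks only.

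The first comparison asks where JARID1B sits relative to the marks it removes. In MCF7, 67.7% of JARID1B peaks (95% Wilson interval 67.1 to 68.4) lay on an H3K4me3 peak, against 1.42% by chance. A further 9.21% lay on H3K4me2 without H3K4me3, and 23.0% on neither mark. Seen from the mark, 34.4% of MCF7 H3K4me3 peaks held a JARID1B peak. That share was 67.6% among the widest H3K4me3 peaks (the fourth quartile by width) and 8.29% among the narrowest. The region with the highest mean rank of both, chromosome 1 from 228673974 to 228676520, spanned 2547 bp. It was followed by chromosome 17 from 80170218 to 80171756 and chromosome 19 from 41168435 to 41169693. With a reciprocal overlap of 50% the MCF7 share was 2.65%, since JARID1B peaks are much narrower than H3K4me3 peaks.

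JARID1B peaks on H3K4me3 of their own line were a smaller share in both basal lines with marks, whose H3K4me3 lists were also smaller, covering 18.0 Mb in SUM159PT and 15.2 Mb in HCC2157 against 25.5 Mb in MCF7. In SUM159PT, 35.0% (34.3 to 35.6) lay on H3K4me3, against 0.917% by chance, and 20.1% on H3K4me2 without H3K4me3. In HCC2157, 14.6% (14.2 to 15.0) lay on H3K4me3, against 0.756% by chance, and 75.7% lay on neither mark of that line. On the MCF7 H3K4me3 list the shares were higher, 41.8% (41.1 to 42.5) of SUM159PT and 24.1% (23.6 to 24.6) of HCC2157 JARID1B peaks, and still below the MCF7 share. The HCC2157 JARID1B peaks also lay more often on H3K4me3 of SUM159PT, at 17.3%, and on H3K4me2 of MCF7, at 32.6%, than on H3K4me3 and H3K4me2 of HCC2157, the latter at 17.4%. The widest H3K4me3 peaks again held JARID1B more often than the narrowest, 49.9% against 13.8% in SUM159PT, and 1556 against 524 of 6223 peaks in HCC2157. The reciprocal rule gave 1.31% in SUM159PT and 0.532% in HCC2157, the upper-scored peaks of both lists gave 19.5% in SUM159PT, and the midpoint rule gave 6.21% in HCC2157. Whether the lines differ beyond the spread between libraries cannot be tested with 1 library each.

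The SUM159PT libraries show how often JARID1B and CTCF occupy the same sites. In this line 62.6% of JARID1B peaks (61.9 to 63.2) lay on a CTCF peak, against 0.566% by chance, and 40.0% of the 31939 CTCF peaks held JARID1B. The share of JARID1B peaks on CTCF was 45.0% in the lowest JARID1B score quartile and 84.7% in the highest. Likewise, 18.3% of CTCF peaks in the lowest CTCF score quartile and 69.5% in the highest held JARID1B. CTCF sites with neither mark made up 24.6% of JARID1B peaks, and 23.1% carried both CTCF and H3K4me3. On H3K4me3, 66.0% of JARID1B peaks also lay on CTCF, against 60.7% elsewhere, a difference of 5.30 points (3.24 to 7.51). The highest shared ranks were at chromosome 11 from 130731838 to 130732200, chromosome X from 153763069 to 153763462 and chromosome 20 from 56784894 to 56785186. The first of these also carried H3K4me3 in at least 1 line, and the others did not.

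**Figure D1:**
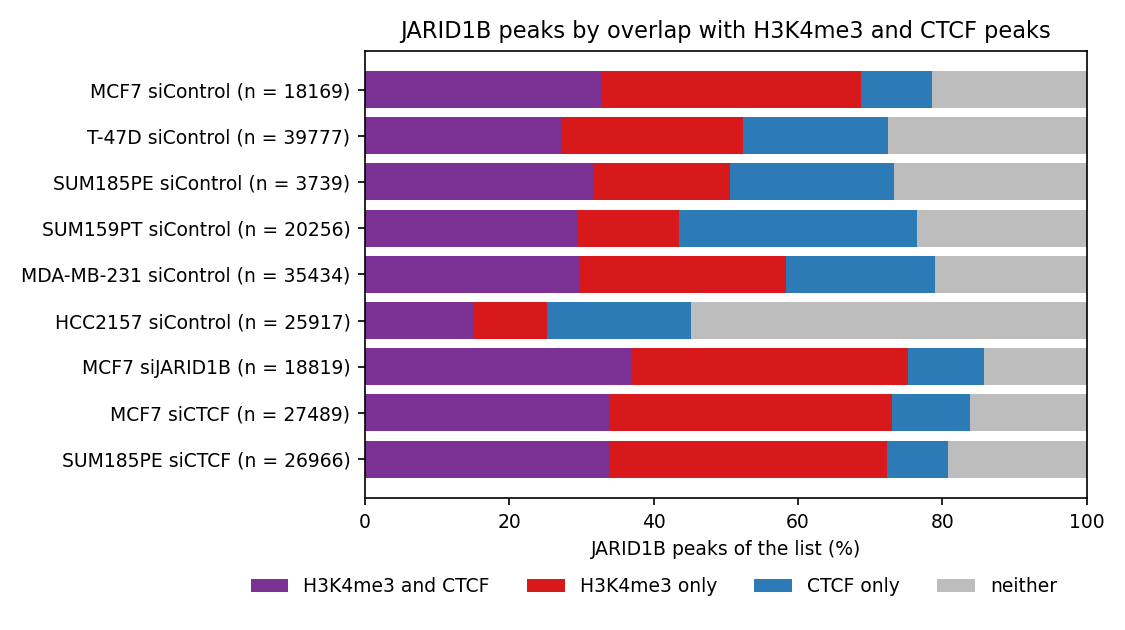
Percent of the peaks in each of the 9 JARID1B lists (x axis) that overlap peaks of H3K4me3 in any of 3 lines and of CTCF in SUM159PT, both, or neither; n is the number of peaks per list. Peaks on neither reach 54.9% in HCC2157 and lie between 14.2% and 27.5% in the other lists.

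Knockdown of JARID1B asks which peaks of its own antibody are lost. The library labelled siJARID1B held 18819 JARID1B peaks, 1.04 times the siControl number, so its list was not shorter than the control list. Of the MCF7 siControl peaks, 69.4% (68.8 to 70.1) were also called in that library, against 0.428% by chance. Peaks on both H3K4me3 and CTCF sites were kept at 89.3%, those on H3K4me3 only at 72.4%, those on CTCF sites only at 77.6%, and those on neither at 31.7%. Within each score quartile, peaks on H3K4me3 only were kept more often than those on CTCF sites only, at 57.8% against 40.0% in the lowest and 97.1% against 93.1% in the highest, the reverse of their order over all peaks. Retention followed the score, with 44.9% kept in the lowest score quartile and 96.0% in the highest. The highest-scored peaks missing from the library labelled siJARID1B were at chromosome 14 from 102990917 to 102991083, ranked 873 of the siControl list, and chromosome 1 from 108293116 to 108293275. In the other direction, 65.6% of the peaks labelled siJARID1B were in the siControl list.

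H3K4 methylation after siJARID1B was then compared in MCF7, since JARID1B removes this mark. Of the 66746 H3K4me2 peaks in the library labelled siJARID1B, 22.7% (22.4 to 23.0) had no siControl peak, and 14.0% of the 55007 siControl peaks had no counterpart. For H3K4me3, 15.0% (14.6 to 15.4) of 29047 peaks had no siControl peak, and 5.58% of 27132 siControl peaks were missing. By chance 97.2% and 97.8% would have lacked one. The peaks without a siControl counterpart were narrow, with a median of 181 bp for H3K4me2 against 412 bp for shared peaks, and 184 bp against 915 bp for H3K4me3. The siControl peaks missing under siJARID1B were narrow too, at 177 bp against 438 bp for H3K4me2 and 173 bp against 836 bp for H3K4me3. On JARID1B peaks themselves, 1.07% of H3K4me2 peaks and 0.639% of H3K4me3 peaks had no siControl counterpart, against 27.2% and 21.6% off them. Peaks on JARID1B were mostly high-scored, with 7888 of 11468 H3K4me2 peaks and 4902 of 9228 H3K4me3 peaks in the highest score quartile. In the lowest score quartile the shares on JARID1B peaks were 15.8% and 13.4%, against 54.1% and 53.3% of all peaks in that quartile. Of the H3K4me3 peaks without a siControl counterpart, 61.9% lay on a siControl H3K4me2 peak, against 91.5% of all H3K4me3 peaks in the library labelled siJARID1B. Of the siControl H3K4me3 peaks that were missing, 87.7% did, against 95.3% of all siControl H3K4me3 peaks. Among H3K4me2 peaks without a siControl counterpart, the highest-scored were at chromosome 1 from 228784549 to 228784887 and chromosome 2 from 43749 to 44169. For H3K4me3 they were at chromosome 9 from 74978291 to 74978585 and chromosome 12 from 54335022 to 54335292.

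In regions called in both libraries, H3K4me3 covered 26.7 Mb under siJARID1B and 25.2 Mb under siControl, a ratio of 1.06, and 68.4% of the 23363 regions were wider under siJARID1B. That share was 69.3% on JARID1B peaks and 67.9% off them. H3K4me2 covered 32.4 Mb against 32.8 Mb, and 37.3% of shared regions on JARID1B peaks were wider, against 48.8% off them. The reciprocal rule raised the share without counterpart to 42.4% for H3K4me2 and 23.3% for H3K4me3. With both lists cut to their upper-scored peaks it was 6.54% for H3K4me3, but a lower-scored siControl peak then no longer counts. Against the full siControl list, 0 of the 14523 upper-scored H3K4me3 peaks lacked a counterpart.

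**Figure D2:**
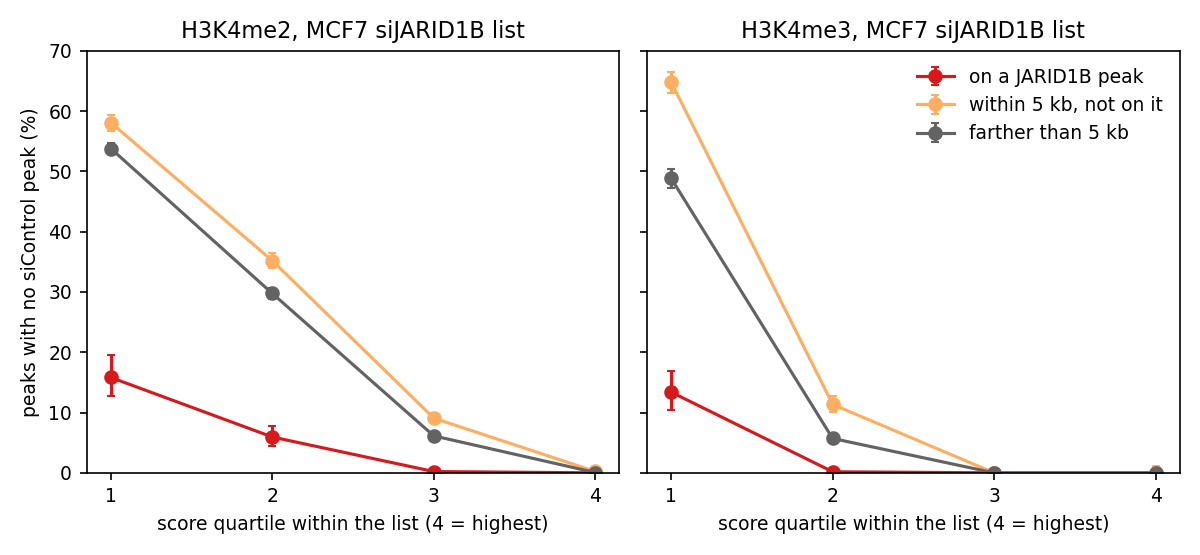
Percent of H3K4me2 (left) and H3K4me3 (right) peaks of the MCF7 siJARID1B lists with no siControl peak (y axis), by score quartile within the list (x axis) and by position relative to siControl JARID1B peaks; bars are 95% Wilson intervals. In the lowest score quartile H3K4me3 reaches 64.8% within 5 kb of a JARID1B peak, 48.8% farther away and 13.4% on it.

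Knockdown of CTCF asks whether JARID1B peaks depend on it. In MCF7 the siCTCF list held 27489 JARID1B peaks, 1.51 times the siControl number, and 69.4% of siControl peaks (68.8 to 70.1) were also called, against 0.604% by chance. The 7782 peaks on CTCF sites, with or without H3K4me3, were kept at 86.1% after siCTCF and 86.5% in the library labelled siJARID1B. That difference was -0.398 points (-1.44 to 0.667). Peaks off CTCF sites were kept at 56.9% after siCTCF. Peaks on CTCF sites without H3K4me3 were kept at 66.0% after siCTCF, which is 11.6 points below their retention in the library labelled siJARID1B (difference -11.6, interval -14.1 to -8.85). Peaks on neither were kept at 22.2%, a difference of -9.49 (-11.2 to -7.40). Peaks on H3K4me3 only were kept at 78.8%, a difference of 6.43 (5.13 to 7.70), and those on both at 92.3%, a difference of 3.08 (2.17 to 3.97). With the lists at equal length the difference was -15.0 for CTCF only, -13.9 for neither, -10.2 for H3K4me3 only and -5.19 for both, so the last pair turned direction. The highest-scored siControl peaks missing after siCTCF were at chromosome 19 from 18977435 to 18977667, ranked 35, and chromosome 17 from 79075605 to 79075844, ranked 211. Both lay on CTCF sites and were present in the library labelled siJARID1B. The reciprocal rule gave 45.6% kept.

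The lists from both knockdowns overlapped in what they lacked. Of the 18169 MCF7 siControl peaks, 10667 were kept in both and 3606 were missing from both, where independent lists would give 8759 and 1698. Retention in both depended on the score and class of the peak, and lists independent within score quartiles would give 9268 and 2207, or 10032 and 2971 within score quartiles and the 4 classes by H3K4me3 and CTCF sites. Both comparisons use the same siControl library, so part of the excess may come from the shared control, and lists without read counts allow no simulation of it.

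In SUM185PE, 70.6% (69.2 to 72.1) of the 3739 siControl peaks were also called after siCTCF, against 0.486% by chance. The siCTCF list held 26966 peaks, 7.21 times as many, and only 9.69% of these were in the siControl list. Peaks on H3K4me3 and CTCF sites were kept at 96.6%, those on H3K4me3 only at 89.7%, those on CTCF sites only at 69.7% and those on neither at 27.2%. The siCTCF list lay on H3K4me3 of any of 3 lines for 72.3% of its peaks, against 50.5% under siControl, and on CTCF sites without H3K4me3 for 8.46%, against 22.8%. On all CTCF sites the shares were 42.2% after siCTCF and 54.4% under siControl, a difference of -12.1 points that turned to 16.8 points with lists of equal length. At equal length the difference for CTCF sites without H3K4me3 was -7.11 points. The highest-scored peaks of the siCTCF list with no siControl peak were at chromosome 11 from 118306640 to 118307189, ranked 2, and chromosome 10 from 103329927 to 103330335. Those missing after siCTCF were led by chromosome 7 from 130692204 to 130692493 and chromosome 16 from 49441941 to 49442111, neither on H3K4me3 nor on a CTCF site. Retention was 40.2% with lists of equal length and 38.5% under the reciprocal rule.

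**Figure D3:**
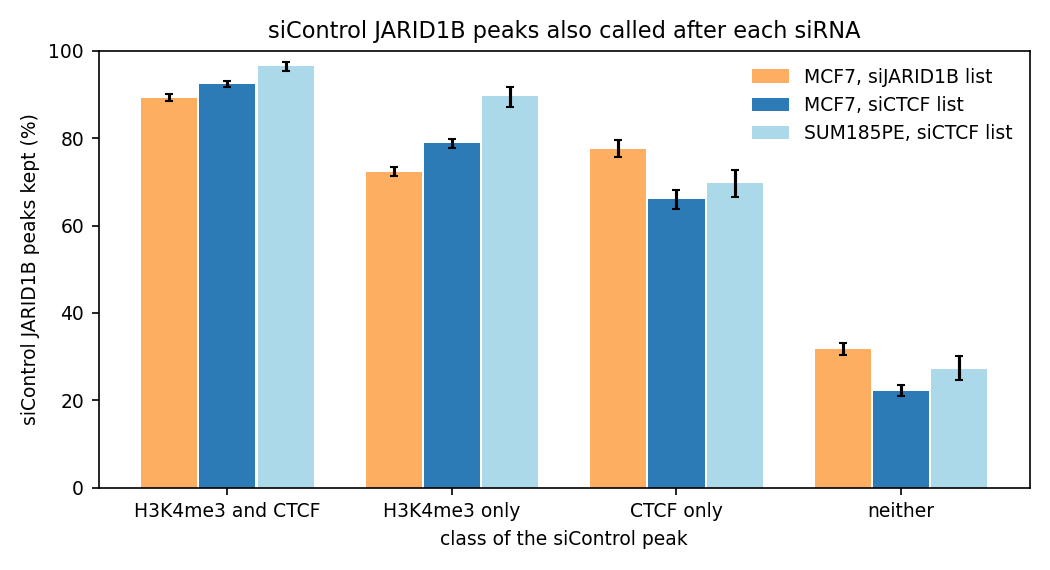
Percent of siControl JARID1B peaks also called in each knockdown list (y axis) by the class of the siControl peak (x axis); bars are 95% Wilson intervals. In all 3 comparisons retention is highest on H3K4me3 with CTCF, between 89.3% and 96.6%, and lowest on neither, between 22.2% and 31.7%.

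Across the 6 lines under siControl, JARID1B peaks joined into 70055 regions, of which 38383 (54.8%) were found in 1 line and 1522 (2.17%) in all 6. Regions in more lines lay more often on CTCF sites, from 12.7% of those in 1 line to 88.6% of those in all 6. These sites were mapped in SUM159PT, which held each region of all 6 lines but only 3487 of those in 1 line. Part of the rise may therefore come from the map, although 21.4% of these 3487 lay on CTCF sites. The share on H3K4me3 was 26.7% in 1 line and 76.1% in all 6, but fell from 57.9% in 3 lines to 51.9% in 4. Regions in all 6 lines with the highest mean rank were at chromosome 16 from 89752862 to 89753480 and chromosome 1 from 12289883 to 12290204, both on H3K4me3 and CTCF sites. The largest set shared by exactly 3 lines was that of MCF7, T-47D and MDA-MB-231, with 2755 regions. Of these 91.8% lay on H3K4me3 and 51.7% on CTCF sites. T-47D, SUM159PT and MDA-MB-231 shared 2171, of which 49.9% lay on H3K4me3 and 82.7% on CTCF sites.

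**Figure D4:**
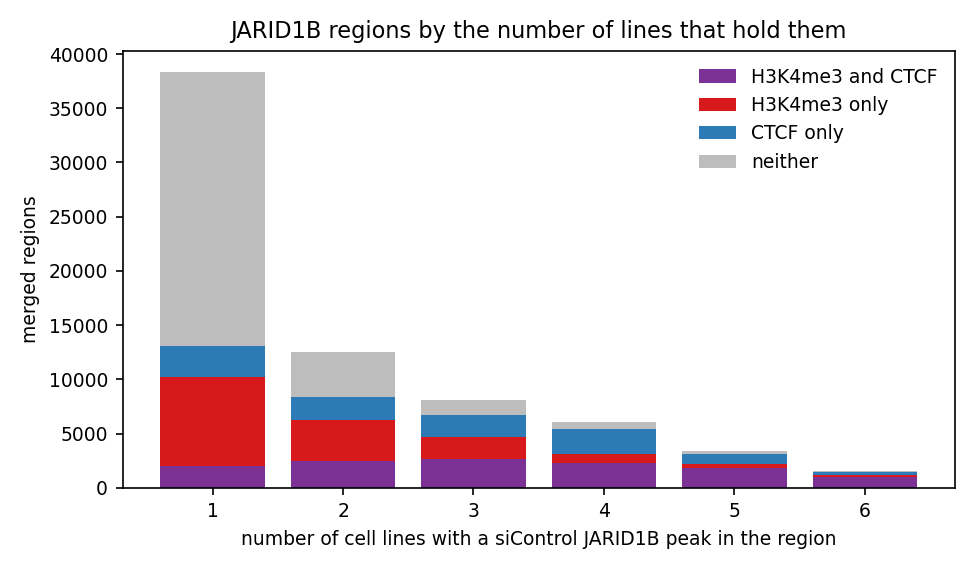
Number of merged JARID1B regions (y axis) by the number of lines with a siControl peak in the region (x axis, 1 to 6), divided by overlap with H3K4me3 and CTCF peaks. Regions on neither fall from 65.9% of those in 1 line to 1.71% of those in all 6.

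Luminal and basal lines were compared because JARID1B has been studied as a regulator of the luminal state. Exactly 23 regions were found in the 3 luminal lines and no basal line, and 385 in the 3 basal lines and no luminal line. The first luminal regions by rank were at chromosome 5 from 174871603 to 174871992, chromosome 17 from 3907985 to 3908212 and chromosome 10 from 8096248 to 8097363. A second region of the same chromosome 10 locus, from 8093682 to 8094231, was also among the 8. The first basal regions were at chromosome 12 from 104609418 to 104609739 and chromosome 16 from 57836291 to 57836599, both on H3K4me3 and CTCF sites. Of the basal regions 50.9% lay on CTCF sites and 11.7% on H3K4me3, and of the 23 luminal regions 8.70% and 78.3%. CTCF was mapped in SUM159PT only, where each basal region and no luminal region held a JARID1B peak. The H3K4me3 list that covered most was that of MCF7, where each luminal region and no basal region held one. These shares therefore depend on which lines gave the maps and do not separate the subtypes. The short SUM185PE list limits the luminal count, which was 1049 without that line, beside a basal count of 417 without it. Without SUM185PE a luminal region has to be in fewer lines than a basal region, so these 2 counts are not alike. The luminal count was 3.48 times as high without MCF7, 2.04 times without T-47D, 5.26 times without MDA-MB-231 and 2.26 times without HCC2157. With lists of equal length, HCC2157 being drawn at random and the others cut by score, the luminal count was 62 and the basal count 38. Their order turned, but a random draw can drop strong HCC2157 peaks, which can lower the basal count and raise the luminal count. The turn therefore decides nothing. The basal count was 3391 without T-47D, 821 without SUM159PT, 863 without MDA-MB-231 and 1455 without HCC2157.

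The share of JARID1B peaks on H3K4me3 of any line was 68.7% in MCF7, 52.3% in T-47D and 50.5% in SUM185PE, with a mean of 57.2% over the luminal lines. It was 43.5% in SUM159PT, 58.3% in MDA-MB-231 and 25.2% in HCC2157, with a mean of 42.3% ± 16.6 (SD, n = 3) over the basal lines. The difference could not be told apart from the spread between lines (two-sided exact permutation test p = 0.3, adjusted p = 0.9 over 4 measures). The share on CTCF sites averaged 48.2% ± 5.81 (SD, n = 3) and 49.2% ± 13.9 (SD, n = 3), with exact permutation p = 0.9. With 3 lines against 3, the smallest p these tests allow is 0.1, so a lack of difference is not shown. Lines of the same subtype shared on average 21.1% of the regions of each pair, and lines of different subtypes 21.7%.

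The marks themselves differed between lines. Of 29627 merged H3K4me3 regions in MCF7, SUM159PT and HCC2157, 13014 (43.9%) were in all 3 lines, with a median width of 1476 bp. MCF7 alone held 8807, with a median of 253 bp. JARID1B was present in MCF7 on 50.9% of the regions shared by all 3 lines and on 17.1% of those of MCF7 alone. The highest-ranked MCF7 H3K4me3 peaks missing in SUM159PT were at chromosome 1 from 3370736 to 3372392 and chromosome 4 from 184826218 to 184827601. Of the SUM159PT peaks missing in MCF7, chromosome 15 from 23810469 to 23812108 ranked first. The MCF7 count was 2723 for the upper-scored peaks and 4328 with lists of equal length.

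For H3K4me2, 33.0% (32.6 to 33.4) of the 55007 MCF7 peaks were in neither SUM159PT nor HCC2157, against 94.98% by chance. Regions in all 3 lines numbered 16239, of which 46.3% held JARID1B in MCF7, while 6.25% of the 18146 MCF7-only regions did. SUM159PT alone held 33559 H3K4me2 regions, and 3.96% of them carried JARID1B in that line. The share for MCF7 was 54.1% under the reciprocal rule and 20.1% among upper-scored peaks.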

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

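The tests of scores near the calling threshold, of SUM185PE peaks at sites of other luminal lines, of SUM185PE peaks on H3K4me3 or CTCF sites and of CTCF shares at equal list length were chosen after the results were seen. The remaining tests below were stated before their results were seen.

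With full lists, the share of JARID1B peaks on CTCF sites moved in opposite directions after siCTCF in the 2 lines, each with 1 library per condition, and the difference was not tested. The share of peaks on CTCF sites differed, siCTCF minus siControl, by 1.67 points in MCF7 and -12.1 points in SUM185PE. For CTCF sites without H3K4me3 of any of 3 lines the differences were 0.826 points in MCF7 and -14.3 points in SUM185PE. With lists of equal length, chosen after seeing the data, the differences on CTCF sites were 11.3 and 16.8 points, no longer opposite, and those without H3K4me3 were 4.50 and -7.11 points. Outside the chromosomes compared, mitochondrial peaks numbered 16 in the HCC2157 JARID1B list, 12 in SUM159PT JARID1B, 5 in SUM185PE siControl JARID1B and 10 in HCC2157 H3K4me2. These are above 3, the limit that a count of 0 allows, and no control list was available for them here.

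The first pattern weighed is the short SUM185PE siControl list beside a siCTCF list 7.21 times as long. The siCTCF list shortened to 3739 peaks by score had a share on H3K4me3 27.3 points (25.2 to 29.3) higher than the siControl list, beyond the limit of 10 points stated for lower enrichment of the siControl library alone, but that limit was wrong, because background peaks would also give this difference and peaks on neither H3K4me3 nor CTCF sites made up 26.7% of the siControl list and 6.58% of the shortened list. Background peaks added to the same JARID1B sites, alone, are argued against, because among peaks on H3K4me3 or CTCF sites the siCTCF share on H3K4me3 was still 14.3 points higher (12.2 to 16.4) at this length, the smallest difference over 4 lengths from 934 to 26966 peaks. If siCTCF had brought JARID1B to sites outside the siControl lists of the other luminal lines, few of the 24352 added peaks would lie on peaks of MCF7 or T-47D, but 70.7% did. Lower enrichment that affects H3K4me3 and CTCF sites unequally, another difference between the libraries and a change of sites after siCTCF stay open, since 1 library per condition does not separate them.

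The second pattern is the retention of JARID1B peaks in the library labelled siJARID1B. A loss of binding beyond the difference between any 2 MCF7 lists was not seen, because at equal list length retention was 9.88 points higher than after siCTCF. The comparison list is itself a knockdown and there was no second siControl library, so a partial loss of JARID1B matched by a loss after siCTCF is not excluded. Retention was also computed without the windows dense in peaks, which by construction cannot explain the peaks outside them. The 16072 peaks outside these windows were kept at 70.4%, against 69.4% of all 18169 peaks. Retention moved by 0.915 points without the windows, where changes from -3.99 to 9.06 points were possible. The stated limit of 10 points was out of reach, because the windows held too few peaks, so the test decides nothing about the peaks inside them. Residual protein and antibody signal unrelated to JARID1B were not tested and stay open.

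The third pattern is the set of H3K4me2 and H3K4me3 peaks called only in the libraries labelled siJARID1B. Scores near the calling threshold are a candidate explanation, since 6.92% of these H3K4me2 peaks and 0% of the H3K4me3 peaks lay in score quartiles 3 and 4 of their lists, although a weak real gain would look the same. A gain beside JARID1B peaks was tested by comparing peaks within 5 kb with those farther away at equal score quartile, and the differences for H3K4me2 in quartiles 1 to 3 were 4.28, 5.44 and 2.94 points, which met neither the limit of more than 5 points in every quartile nor the opposite one. For H3K4me3 the differences were 15.9 points (13.3 to 18.7) and 5.64 points (4.10 to 7.33) in quartiles 1 and 2, but the test as stated decides nothing, because quartile 3 held no peaks without counterpart at any distance. A gain beside JARID1B peaks stays open for both marks, and fragments of wide domains called separately and depth were not tested.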

How the results depend on the processing

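Percentages were compared with their counting intervals, which are narrow, and of 75 values under alternatives 14 stayed within the limits, 60 moved and 1 turned its sign. No paired analysis was possible because each group has 1 library. Depth per library is unknown, and for values that moved the cause was not tested. With a reciprocal overlap of 50%, retention of JARID1B peaks was 54.1% (MCF7 siJARID1B), 45.6% (MCF7 siCTCF) and 38.5% (SUM185PE siCTCF), new peaks were 42.4% (H3K4me2) and 23.3% (H3K4me3), overlap with CTCF was 49.1%, overlap with H3K4me3 was 2.65% (MCF7), 1.31% (SUM159PT) and 0.532% (HCC2157), and MCF7-only H3K4me2 was 54.1%. With the midpoint rule, retention was 64.7% and 63.7% in MCF7, new peaks were 26.4% and 16.8%, CTCF overlap was 56.8%, H3K4me3 overlap was 64.2%, 27.1% and 6.21%, and MCF7-only H3K4me2 was 38.2%. Among upper-scored peaks, retention after siJARID1B was 70.7%, new peaks were 17.8% and 6.54%, CTCF overlap was 61.4%, H3K4me3 overlap was 57.4% (MCF7) and 19.5% (SUM159PT), and the MCF7-only values were 20.1% (H3K4me2) and 2723 regions (H3K4me3). All lists are cut in this setting, so a peak whose counterpart scored lower counts as lacking one. Against the full siControl lists, new peaks were 3.14% (H3K4me2) and 0% (H3K4me3) of the upper-scored peaks. With lists of equal length, retention was 68.5%, 58.6% and 40.2%, new peaks were 15.3% and 11.1%, CTCF overlap was 51.5%, MCF7 H3K4me3 overlap was 63.7%, and the MCF7-only values were 26.6% and 4328 regions. Without the densest windows, retention was 70.4% and 71.2% in MCF7, new H3K4me2 peaks were 23.0%, and H3K4me3 overlap was 69.8%, 34.2% and 14.1%. Leaving out each line in turn gave 33 to 1049 luminal-only and 417 to 3391 basal-only regions, since fewer lists have to hold or lack a region. In 2 alternatives chosen after seeing the data, HCC2157 peaks were drawn at random and the other lists were cut by score. Lists of equal length gave 62 luminal-only and 38 basal-only regions, and lists of equal length without SUM185PE gave 915 and 617. In both alternatives the luminal count exceeded the basal count, as it did without SUM185PE at full length. The random draw can drop strong HCC2157 peaks, which can favour this order. Leaving out SUM185PE can favour it too, since a luminal region then has to be in fewer lines than a basal region. In further alternatives chosen after seeing the data, lists of equal length gave siCTCF minus siControl differences of 16.8 points on CTCF sites in SUM185PE, the value that turned, and 11.3 in MCF7, -7.11 and 4.50 points on CTCF sites without H3K4me3, and 27.3 and 2.89 points on H3K4me3. Upper-scored and equal-length values that need ranks of the HCC2157 JARID1B list, and promoter windows, were not run.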

Other observations

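The test of other groupings of the lines, with full lists and with lists of equal length, was chosen after the result was seen.

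The HCC2157 JARID1B list stood apart in where its peaks lay. Of its 25917 peaks, 54.9% (54.3 to 55.5) were on neither H3K4me3 of any of 3 lines nor a CTCF site, which includes 10.4% on H3K4me2 of any of the 3 lines. Regions found in HCC2157 alone numbered 10855, of which 92.5% were on neither. Of regions found in 1 other line alone, 87.8% were on neither in SUM185PE, 64.9% in MCF7, 64.6% in SUM159PT, 54.3% in T-47D and 47.3% in MDA-MB-231. The HCC2157 JARID1B list is also the one whose peaks all have the score 1.

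The SUM159PT window on chromosome 8 from 128000001 to 129000000 held 131 JARID1B peaks, 21.8 times that list's median window, and its CTCF peaks there were 12.6 times the median window of their list. It held 9 H3K4me3 peaks in SUM159PT, and under siControl it held 14 JARID1B peaks in MCF7, 17 in T-47D, 2 in SUM185PE, 15 in MDA-MB-231 and 44 in HCC2157. Relative to list length, H3K4me2 peaks in this window were also more frequent in SUM159PT than in MCF7 or HCC2157. For H3K4me3 the SUM159PT frequency lay between those of the MCF7 siControl and siJARID1B lists. The input samples were not analysed, so whether the excess in this window is specific to the targets was not tested. In MCF7 the densest JARID1B window was chromosome 8 from 144000001 to 145000000, with 147 siControl peaks and 125 in the library labelled siJARID1B. The densest MDA-MB-231 window, chromosome 19 from 1000001 to 2000000, held 203 JARID1B peaks.

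In the lowest score quartile, siControl H3K4 peaks missing in the libraries labelled siJARID1B were fewer within 5 kb of JARID1B peaks than farther away. There, 27.5% of siControl H3K4me2 peaks within 5 kb of a JARID1B peak were missing, against 40.7% farther away, a difference of -13.2 points (-15.1 to -11.2). For H3K4me3 the shares were 14.3% and 22.7%, a difference of -8.47 points (-10.5 to -6.43). In quartile 2 the differences were -5.40 points (-6.70 to -4.15) for H3K4me2 and -0.354 points (-0.806 to 0.154) for H3K4me3. Over all quartiles, 7.12% of H3K4me3 peaks within 5 kb were missing and 7.02% farther away. On JARID1B peaks themselves the shares in the lowest quartile were 49.6% for H3K4me2 and 44.3% for H3K4me3.

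Regions that separate the subtypes, in either direction, numbered 408. The highest number from another division of the 6 lines into 3 and 3 was 2797, for MCF7, T-47D and MDA-MB-231 against the rest, and 5 of the 10 splits, that by subtype included, gave at least 408. With lists of equal length the same division was again the highest, with 292 regions, against 62 luminal-only and 38 basal-only regions. That division joins the longest lists, T-47D with 39777 peaks and MDA-MB-231 with 35434, and has the shortest, SUM185PE with 3739, on its other side. List length may therefore give much of the full-list number. At equal length HCC2157 peaks were drawn at random, which can raise the number of regions that HCC2157 lacks. The source of the remaining difference was not tested. The 10 possible splits are too few for a share under 0.05.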
